A study of Mus musculus with 6 samples.

How the data were processed

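Regulatory T cells (Treg cells) were isolated by fluorescence-activated sorting from C57BL/6 mice, per the labels and the series' design text. Total RNA was extracted with a miRNeasy kit and biotin-labelled cRNA was made from 2 ug of it, per the labels' protocols. The labels place 6 arrays in 4 groups: wild type (WT, 2 arrays), Foxo1 knockout (Foxo1KO, 2 arrays), mice with a constitutively active form of Foxo1 (Foxo1AAA, 1 array), and Foxo1 knockout mice with that form (Foxo1KO/Foxo1AAA, 1 array). No label states that the replicates were separate mice, so p-values measure the spread between these arrays. The Y chromosome gene Eif2s3y measured 3.91 and 10.09 on the WT arrays and 4.05 and 9.91 on the Foxo1KO arrays, and Kdm5d and Uty differed likewise. These values argue against repeat arrays of the same RNA in either group. Whether an array held 1 mouse or a pool was not given. The sorting gates, the ages and sexes of the mice, the deleted part of Foxo1 and the site of the Foxo1AAA transgene were not given in the sources used here.

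The deposited values were on the log2 scale. RMA, which corrects background, quantile-normalizes arrays together and summarizes the probes of each probe set, was used with R 2.15 and limma 3.12.1, per the submitters' processing notes. Quantile normalization gives every array nearly the same distribution of values, so a shift of most transcripts in one direction would be hidden. Array values also saturate at high signal and flatten near background, so differences of very bright or very dim probe sets are understated. Folds of genes with a dim lower group are therefore given as lower bounds. Log2 differences of such genes are lower bounds in size too, also where the text does not repeat it. The number of arrays limits the precision. A group with 1 array had no replicate check of its own.

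Of the 45101 probe sets on the array, 34958 were listed with 1 gene in the platform annotation, 932 with several genes, and 9211 were not listed. Symbols were updated through their Entrez identifiers. Probe sets with several genes or none were left out of the gene analysis. For each of the 18194 genes the probe set with the highest mean over the 6 arrays was kept, which mattered for the 9012 genes with more than 1 probe set. Genes in the lowest 25% by mean over all arrays were then left out, leaving 13645 tested genes with a mean of at least 5.47. Tcf7, which belongs to several of the gene lists, had no probe set listed under its name in that annotation and was not analysed here. The probe set of Foxp3 fell below the filter and was tested only with every probe set.

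The log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 4 groups and an empirical Bayes prior on the variance. The residual spread came from the WT and Foxo1KO pairs alone and had 2 degrees of freedom. The prior had 6.59 degrees of freedom and an SD of 0.10 log2 units. The lone Foxo1AAA and Foxo1KO/Foxo1AAA arrays were assumed to vary like those pairs, and this could not be checked. The 5 comparisons of groups were Foxo1KO with WT, Foxo1KO/Foxo1AAA with Foxo1KO, Foxo1AAA with WT, Foxo1KO/Foxo1AAA with WT, and Foxo1KO/Foxo1AAA with Foxo1AAA. An interaction contrast tested whether the knockout difference was the same with and without Foxo1AAA. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used for single genes.

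Gene sets comprised 23 lists: Foxo targets, Treg signature, effector Treg, naive and central T cell, Th1, Th2, Th17, follicular helper, trafficking receptors, immediate early genes of T cell receptor signalling, cell cycle, apoptosis, glycolysis, autophagy, PI3K and mTOR, interferon response, heat shock, and markers of B cells, myeloid cells, dendritic cells, CD8 T and NK cells, conventional CD4 T cells and erythroid cells. Each list was tested with camera from limma, which compares a list's differences with those of all other genes, at a preset correlation of 0.01 between genes, and p was adjusted over the 23 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance in one direction. With an estimated correlation camera rests on the 2 residual degrees of freedom and has little power. The estimates themselves lay far above the preset for some lists: 0.57 for cell cycle, 0.46 for effector Treg, 0.73 for B cell and 0.82 for dendritic cell markers. For Foxo targets (0.025) and heat shock (-0.060) they lay near it or below. Where a list's genes vary together more than the preset allows, camera's p at the preset is too small. A list not called in that setting is therefore not shown to be unshifted. Counts of called members were made over all tested genes and adjusted over the list alone.

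For the genes changed in Foxo1KO, the share recovered was the difference between Foxo1KO/Foxo1AAA and Foxo1KO divided by the difference between WT and Foxo1KO. The Foxo1KO arrays enter both parts of this ratio, so 100 data sets were simulated with no recovery and no difference between the array pairs. They give the value that selection alone produces when the Foxo1AAA arrays differ in nothing else. Because the Foxo1AAA arrays differed from the others in several ways, a slope was also computed between differences that share no array: Foxo1KO/Foxo1AAA minus Foxo1AAA on Foxo1KO minus WT. A slope of 1 corresponds to the same knockout difference with and without Foxo1AAA, and a slope of 0 to none with it. A slope near 0 does not by itself show a return to WT, since both arrays with Foxo1AAA can lie away from WT.

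The groups, tests, gene lists and the rule for named genes were chosen before the data were examined. The rule names, among others, Foxo1, Foxo3, Foxo4, Foxp3, Il7r, Ccr7, Klf2, Ctla4 and Ifng. For each comparison it adds the 10 higher and the 10 lower called genes with the largest difference whose group values do not overlap. For each list it adds up to 2 higher and 2 lower called members, or the 2 members with the smallest p where none was called. For recovery it adds the 5 genes with the largest and the 5 with the smallest share among genes at least 2-fold changed.

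The fit was tested on simulated data with the real means and 200 genes changed in each of 5 runs over 13645 genes. The SD of each gene was drawn from the prior of the fit, and the noise was independent and alike on every array. In the simulated comparison of Foxo1KO with WT, 37.0% of genes changed by 0.5 log2 units were called, 98.5% of those changed by 1, and 100% of those changed by 2. In the simulated comparison of Foxo1AAA with WT the shares were 11.6%, 93.4% and 100%. Of the calls, 4.85% and 4.48% were false in these comparisons. Since the simulated data follow the model of the fit, these shares do not check its error rate on the real arrays, least of all the lone ones. Alternatives included other filters on dim genes, the mean of all probe sets of a gene, a test of every probe set, cyclic loess and median centring, other variance priors, other thresholds, leaving out each replicated array and using the replicate number as a block.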

Results

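Transcript levels were measured on 6 oligonucleotide arrays in Treg cells, the CD4 T cells that restrain immune responses under the control of the transcription factor Foxp3. Foxo1 is a forkhead transcription factor that leaves the nucleus when Akt phosphorylates it, and Foxo1AAA is a constitutively active form of it. WT and Foxo1KO cells were measured on 2 arrays each, and Foxo1AAA and Foxo1KO/Foxo1AAA cells on 1 array each. The design asks which genes depend on Foxo1 in Treg cells and whether their expression returns in the knockout when Foxo1AAA is present. Replicate arrays correlated at r = 0.996 across all probe sets in both replicated groups, and the median gene differed by 0.10 log2 units between the WT arrays and by 0.11 between the Foxo1KO arrays. The Foxo1AAA and Foxo1KO/Foxo1AAA arrays correlated at r = 0.994 with each other and at 0.971 to 0.980 with the other 4 arrays, whereas WT and Foxo1KO arrays correlated at 0.984 to 0.985. Genes are not independent replicates in these correlations.

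The targeted gene was checked first. Foxo1 had 4 probe sets, and 3 of them lay well above background. These 3 were lower in Foxo1KO than in WT by log2 -0.49, -0.54 and -0.43 (adjusted p over all probe sets = 0.035, 0.023 and 0.070). The same 3 were lower in Foxo1KO/Foxo1AAA than in Foxo1AAA by -0.85, -0.92 and -1.05 (adjusted p = 0.10, 0.092 and 0.082). The 4th probe set, with a WT mean of 4.78, differed by 0.09 between Foxo1KO and WT. The deleted part was not given, and a probe set outside it checks nothing, so these values do not establish how complete the deletion was. In the gene analysis Foxo1 fell by 0.43 in Foxo1KO (WT 11.19 ± 0.23, Foxo1KO 10.76 ± 0.16, SD, n = 2 each, adjusted p = 0.045). This call ended without Foxo1KO replicate 1 (adjusted p = 0.063), Foxo1KO replicate 2 (0.22) or WT replicate 2 (0.24, with a difference of -0.27), and the adjusted p ranged from 0.0098 to 0.24 over the alternatives. Foxo3 differed by 0.02 (adjusted p = 0.93) and Foxo4 by -0.06 (adjusted p = 0.78), and neither was called. The probe set of Foxp3 lay between 5.10 and 5.58 on the 6 arrays, with a mean below the filter of the gene analysis. Tested with every probe set it differed by 0.22 between Foxo1KO and WT (adjusted p = 0.24). It was the only probe set of the gene, and differences of such dim probe sets are understated. The value therefore does not show whether Foxp3 changed.

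The comparison of Foxo1KO with WT addressed which transcripts depend on Foxo1. Granzyme A (Gzma) rose most, at least 101-fold, from 5.95 ± 0.04 in WT to 12.61 ± 0.17 in Foxo1KO (SD, n = 2 each, log2 difference 6.66, SE 0.11, adjusted p = 1.6e-08). Granzyme B (Gzmb) rose 21.3-fold (log2 4.41, SE 0.10, adjusted p = 1.1e-07), and Ifng, the signature cytokine of Th1 cells, rose 5.0-fold (log2 2.32, SE 0.13, adjusted p = 8.1e-06). In the other direction, St8sia6, a sialyltransferase, fell at least 30.8-fold (log2 -4.95, SE 0.13, adjusted p = 2.5e-07), and Nrp1, a surface receptor carried by Treg cells of thymic origin, fell 9.28-fold (log2 -3.21, SE 0.11, adjusted p = 6.6e-07). All 41 measured cell cycle genes rose, while 22 of 27 genes of naive and central T cells fell.

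The other largest rises were those of Ermn (4.41), the transcription factor Arnt2 (4.33), the chemokine receptor Ccr1 (4.09), the NK cell receptor Klrc1 (4.04), Atp8b4 (3.94), the interferon-inducible membrane proteins Ifitm2 (3.92) and Ifitm1 (3.82), and Anxa1 (3.86), all in log2 units. The other largest falls were those of H2-Ob (-3.95), Prg4 (-3.34), Btbd11 (-3.31), Gpr34 (-2.88), A530021J07Rik (-2.80), the ecto-5'-nucleotidase Nt5e (-2.76), Ms4a6c (-2.71) and Gsta4 (-2.69). The Foxo1KO means of H2-Ob, Prg4, Gpr34 and A530021J07Rik and the WT means of Ermn, Ccr1 and Klrc1 lay below the dimmest tested mean of 5.47, so these differences are lower bounds in size and their order is not fixed. The largest SE of these genes was 0.23, and their adjusted p ranged from 1.1e-07 to 1.1e-05.

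**Figure D1:**
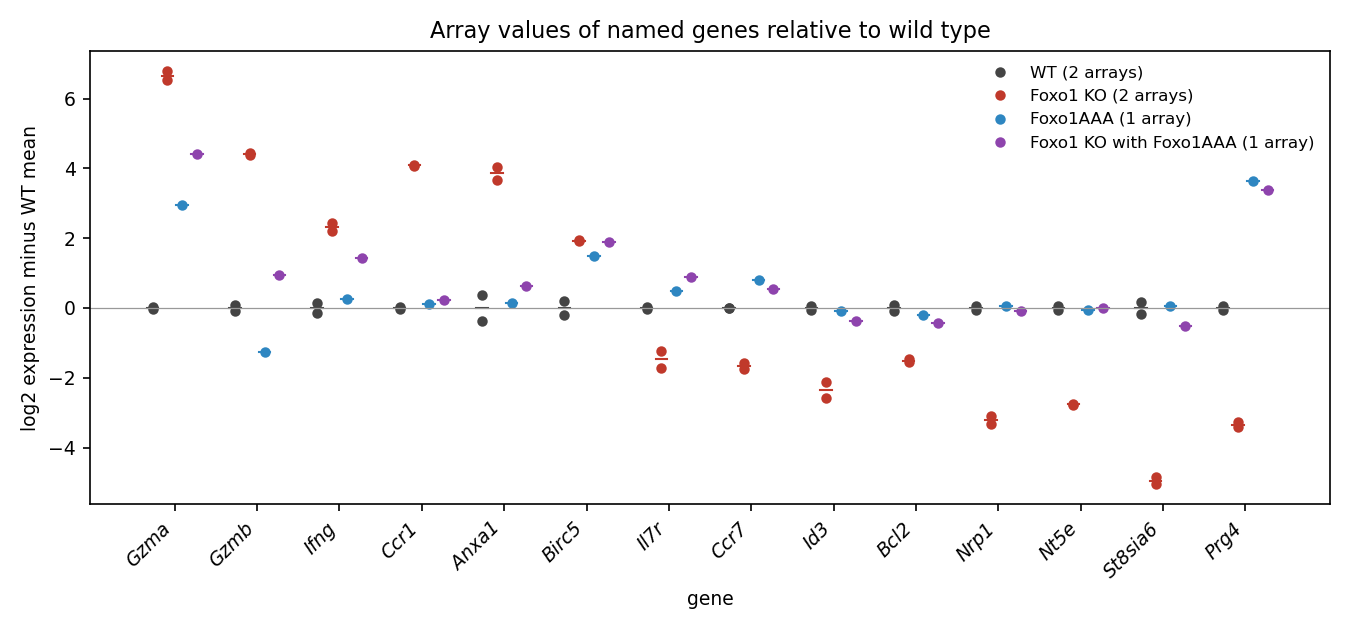
Log2 expression of 14 named genes on each of the 6 arrays, minus the mean of the WT arrays, with a point for each array and a dash for each group mean. Gzma lies 6.66 above WT in Foxo1KO and 4.40 above WT in Foxo1KO/Foxo1AAA, while Prg4 lies 3.34 below WT in Foxo1KO and above WT in both groups with Foxo1AAA.

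Effector genes rose as a group. Of 30 measured members of the effector Treg list, 23 rose and 2 fell (25 and 2 adjusted over the list alone), with a median difference of 0.84 (camera adjusted p = 6.2e-12, adjusted p = 0.32 with an estimated correlation). Gzmb and Anxa1 rose most, and the integrin subunit Itgb1 (-1.62) and the transcription factor Irf4 (-0.74) were the 2 that fell. Of 22 Th1 genes, 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 7.6e-16, adjusted p = 0.32 with an estimated correlation). The CD8 T and NK cell markers moved with these groups: 4 of 7 rose, by both counts, with a median of 0.66 (camera adjusted p = 4.3e-04, adjusted p = 0.32 with an estimated correlation). The 4 included Klrc1, Klrd1 (1.23) and the chemokine Xcl1 (1.27), whereas Cd8a and Cd8b1 differed by 0.19 and 0.18 and were not called. The call of the CD8 T and NK list ended when the lowest 50% of genes were left out (adjusted p = 0.087, range over alternatives 8.4e-05 to 0.087).

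Proliferation genes moved together. The 41 cell cycle genes had a median rise of 1.50 (camera adjusted p = 6.3e-32, adjusted p = 0.32 with an estimated correlation), and all 41 also rose adjusted over the list alone. Birc5 and Aurkb, both of the chromosomal passenger complex, rose by 1.93 and 1.87. Of 17 glycolysis genes, 11 rose and 0 fell (11 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 9.5e-04, adjusted p = 0.32 with an estimated correlation). Among them were Tpi1 (0.94) and Pfkp (0.83). Of 24 interferon response genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 3.2e-06, adjusted p = 0.32 with an estimated correlation), led by Mx1 and Bst2 (1.24 each).

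Genes of naive and central T cells fell. Of 27 measured, 22 fell and 1 rose (22 and 3 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 6.9e-16, adjusted p = 0.32 with an estimated correlation). Dapl1 fell by at least 2.54, a lower bound since its Foxo1KO value was dim, and the transcriptional regulator Id3 by 2.35. The lymph node homing receptor Ccr7 fell by 1.66, the IL-7 receptor chain Il7r by 1.47 and the trafficking regulator Klf2 by 0.68. The chemokine receptor Ccr9 was the 1 member that rose (0.40, adjusted p = 0.014), and its call ended without any of the 4 replicated arrays (adjusted p = 0.063 and 0.064 without Foxo1KO replicates 1 and 2, 0.058 and 0.059 without WT replicates 1 and 2, range over alternatives 0.0081 to 0.42). Of 25 Foxo targets, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 3.4e-04, adjusted p = 0.32 with an estimated correlation). Sesn1 fell by 1.95, while the cell cycle inhibitor Cdkn1a rose by 1.25 and Rbl2 by 0.92. Conventional CD4 T cell markers, 5 of which also belong to other lists, moved the same way: 5 of 10 fell and 0 rose (5 and 1 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.040, adjusted p = 0.32 with an estimated correlation). That call ended without Foxo1KO replicate 2 (adjusted p = 0.077, range over alternatives 0.012 to 0.084).

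Genes of Treg identity moved in both directions. Of 26 measured members of the Treg signature, 10 rose and 6 fell (12 and 7 adjusted over the list alone), with a median of 0.21 and no shift of the list (camera adjusted p = 0.39). Penk rose by 2.06 along with Gzmb, whereas Nrp1 and Nt5e fell. The inhibitory receptor Ctla4 rose by 0.46 (SE 0.14, adjusted p = 0.046). The Ctla4 call ended without Foxo1KO replicate 1 (adjusted p = 0.068), Foxo1KO replicate 2 (0.23) or WT replicate 2 (0.24, with a difference of 0.27), with a range over alternatives of 0.0056 to 0.24.

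Lists of other helper programmes were tested as well. Of 12 Th2 genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.032, adjusted p = 0.32 with an estimated correlation). Il17rb rose by 1.47 and Il4 by 1.44, and the nuclear receptor Pparg fell by 0.81, or by log2 -0.51 without Foxo1KO replicate 2. Without Foxo1KO replicate 1 the Th2 call ended (adjusted p = 0.094, range over alternatives 0.015 to 0.094). Of 13 Th17 genes, 5 rose and 1 fell by both counts, with a median of 0.24 (camera adjusted p = 0.058), and the list was called higher with no filter (0.044, range over alternatives 0.044 to 0.081). Cxcr6 rose by 1.19 and Ccr6 fell by 1.37, and Il21 rose by 0.69, a call that ended without Foxo1KO replicate 1 (0.44, adjusted p = 0.14) or WT replicate 1 (0.071, range over alternatives 0.0035 to 0.14). Of 16 follicular helper genes, 3 rose and 6 fell (4 and 8 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.072). Maf rose by 0.84, and the receptors Slamf6 and Btla fell by 1.51 and 1.30. Without WT replicate 2 this list was called lower (adjusted p = 0.049, range over alternatives 0.028 to 0.21).

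Of 28 trafficking receptors, 12 rose and 8 fell (13 and 10 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.71). Ccr1 and Ccr2 rose by 4.09 and 1.91, and Ccr7 and the integrin subunit Itga4 fell by 1.66 and 1.85. Of 23 immediate early genes of T cell receptor signalling, 5 fell and 1 rose (5 and 2 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.091). Btg2 fell by 1.01 and Egr3 by 0.94, and Fosl2 rose by 0.49. Without WT replicate 2 this list was called lower (adjusted p = 0.017, range over alternatives 0.017 to 0.31). Of 17 apoptosis genes, 5 rose and 2 fell (5 and 4 adjusted over the list alone). Their median was -0.03, whereas their mean was 0.07 and the test pointed up (camera adjusted p = 0.98). Casp1 and Fasl rose by 1.98 and 1.52, and the death promoter Bcl2l11 and the survival gene Bcl2 fell by 1.64 and 1.51.

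Of 18 autophagy genes, Atg7 (0.93) and Bnip3 (0.73) rose and 0 fell, by both counts. The median was -0.01, whereas the mean was 0.08 and the test pointed up (camera adjusted p = 0.87). Of 19 genes of PI3K and mTOR signalling, 4 rose and 3 fell by both counts, with a median of -0.07 (camera adjusted p = 0.60). Sgk1 rose by 1.57 and Ddit4 by 0.96, and Pik3r5 and the Akt phosphatase Phlpp1 fell by 1.59 and 0.80. The Ddit4 call ended without Foxo1KO replicate 2 (0.63, adjusted p = 0.12, range over alternatives 6.6e-04 to 0.12). Of 11 heat shock genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.075). The list was called lower with no filter (0.044) and with the mean of probe sets (0.020, range over alternatives 0.020 to 0.21). Hsph1 and Bag3 fell by 0.59 each, and the Hsph1 call ended without Foxo1KO replicate 1 (adjusted p = 0.068, range over alternatives 0.0032 to 0.068).

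Markers of other cells were measured beside these groups. Of 13 myeloid markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0013, adjusted p = 0.50 with an estimated correlation). Cebpb and the lysozyme gene Lyz1 rose by 1.32 and 1.31. Of 10 dendritic cell markers, 4 rose and 0 fell by both counts, with a median of 0.14 (camera adjusted p = 0.040, adjusted p = 0.70 with an estimated correlation). They included the MHC class II genes H2-Aa (1.61) and H2-Eb1 (1.18). The dendritic cell call ended without Foxo1KO replicate 1 (adjusted p = 0.20) or WT replicate 1 (0.099, range over alternatives 1.7e-04 to 0.20), and the H2-Eb1 call without Foxo1KO replicate 1 (difference 0.71, adjusted p = 0.067, range 0.0011 to 0.13). Without that array H2-Aa differed by 0.98. The H2-Aa call ended with a robust variance prior (adjusted p = 0.17, range over alternatives 3.9e-04 to 0.17). Of 12 B cell markers, Cd22 (0.69) rose and Ighm (-0.67) fell, by both counts, and the list did not shift (median 0.13, camera adjusted p = 0.54). The Ighm call ended without Foxo1KO replicate 2 (-0.43, adjusted p = 0.074, range over alternatives 0.0016 to 0.074), and Ighm was higher in Foxo1KO when all its probe sets were averaged (0.84). Without that same array the B cell list was called higher (adjusted p = 0.020, range over alternatives 0.020 to 0.99). None of 6 erythroid markers was called by either count, with a median of 0.05 (camera adjusted p = 0.87), and the smallest p belonged to Car2 (-0.33) and Alas2 (0.27). Without WT replicate 1 Car2 was called lower (adjusted p = 0.044, range over alternatives 0.044 to 0.49).

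In total 2980 of 13645 genes changed in Foxo1KO, 1523 higher and 1457 lower. Of these, 584 differed at least 2-fold, 373 higher and 211 lower. Among the 23 lists, 12 shifted by camera, 9 higher and 3 lower, 0 did so with an estimated correlation, and 13 did so by fry. The lists called by fry were not the same ones. It did not call the myeloid (fry adjusted p = 0.20) and dendritic cell markers (0.36). It called the Th17 (0.029), follicular helper (0.022) and heat shock lists (0.0021), which camera did not.

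The comparison of Foxo1KO/Foxo1AAA with Foxo1KO asked whether expression returned when Foxo1AAA was present. Among genes lowered in the knockout, Prg4 rose at least 106-fold (log2 6.73, SE 0.12, adjusted p = 4.8e-08), Dapl1 at least 33.0-fold (log2 5.05, SE 0.30, adjusted p = 1.1e-05), Il7r 5.10-fold (log2 2.35, SE 0.18, adjusted p = 4.4e-05) and Ccr7 4.58-fold (log2 2.20, SE 0.12, adjusted p = 8.1e-06). The Prg4 values of 5.25 and 5.10 in Foxo1KO lay below the dimmest tested mean of 5.47. Klf2 rose by 0.67 (SE 0.15, adjusted p = 0.0086). Among genes raised in the knockout, of which 624 of 1523 were called back towards WT and 197 further away, Gzmb fell by 3.46 (SE 0.13, adjusted p = 1.8e-06), Gzma by 2.26 (SE 0.13, adjusted p = 1.0e-05) and Ifng by 0.90 (SE 0.15, adjusted p = 0.0028). Foxo1 itself fell by 1.10 (SE 0.16, adjusted p = 0.0012). Cell cycle genes did not fall as a group: of 41, 11 rose and 2 fell by both counts (median 0.20, camera adjusted p = 0.096), and the list was called higher with no filter (0.015) and with the mean of probe sets (0.030, range over alternatives 0.015 to 0.52). Ube2c (1.04) and Nusap1 (0.96) led the rises, and Rrm2 (-0.75) and Ccnb2 (-0.51) fell. The Ccnb2 call ended without Foxo1KO replicate 2 (adjusted p = 0.080, range over alternatives 0.0081 to 0.080) and the Rrm2 call with the mean of all its probe sets (0.14, range 7.4e-04 to 0.14).

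This comparison also set arrays of different make-up against each other. Xist, the transcript of the inactive X chromosome, fell by 6.59 and was the largest fall. It measured 6.27 on the Foxo1KO/Foxo1AAA array and 13.14 and 12.59 on the Foxo1KO arrays. Many of the other leading rises were of genes known from macrophages, such as Vcam1 (5.31), Adgre4 (4.78), the complement gene C1qb (4.64), the mannose receptor Mrc1 (4.62) and the iron exporter Slc40a1 (4.53). They also included Gja1 (6.14), Atp6v0d2 (5.04) and Hpgd (4.55). The other leading falls were those of Ccr1 (-3.85), Ermn (-3.66), Penk (-3.29), 1500009L16Rik (-3.25), Ctla2a (-3.24), Anxa1 (-3.22), Ccr2 (-3.11) and Jdp2 (-3.02).

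By group, 21 of 27 genes of naive and central T cells rose and 2 fell by both counts (median 0.86, camera adjusted p = 9.7e-09, adjusted p = 0.63 with an estimated correlation), led by Dapl1 and Slamf6 (2.61). Of 25 Foxo targets, 13 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.45, camera adjusted p = 9.6e-04, adjusted p = 0.63 with an estimated correlation). Of 22 Th1 genes, 15 fell and 3 rose (16 and 4 adjusted over the list alone, median -0.76, camera adjusted p = 8.0e-04, adjusted p = 0.79 with an estimated correlation), and the 3 included Ccl3 (1.68) and Gzmk (1.33). Of 30 effector Treg genes, 17 fell and 6 rose (18 and 7 adjusted over the list alone, median -0.58, camera adjusted p = 0.0046, adjusted p = 0.85 with an estimated correlation), and the rises were led by Itgb1 (2.12) and Irf4 (1.85). Immediate early genes rose in 12 of 23 cases and fell in 0 (13 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.0019, adjusted p = 0.79 with an estimated correlation), among them Jun (2.27) and Btg2 (1.49). Heat shock genes rose in 8 of 11 cases (9 adjusted over the list alone, median 0.48, camera adjusted p = 8.0e-04, adjusted p = 0.63 with an estimated correlation), led by Hmox1 (2.21) and Hspa1b (2.01). Beside them, 9 of 13 myeloid markers rose and 2 fell (9 and 3 adjusted over the list alone, median 1.82, camera adjusted p = 8.0e-04, adjusted p = 0.79 with an estimated correlation), including Csf1r (3.56) and Fcer1g (3.20). Of 10 dendritic cell markers, 9 rose and 1 fell by both counts (median 1.02, camera adjusted p = 0.0024, adjusted p = 0.85 with an estimated correlation). Of 12 B cell markers, 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.069). That list was called higher in 8 of 9 alternatives, among them those without Foxo1KO replicate 1 (0.0018) and without WT replicate 1 or 2 (0.039 each), with a range of 0.0018 to 0.22.

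In total 5430 genes changed, 2670 higher and 2760 lower, and of those changed at least 2-fold 564 were higher and 232 lower. With arrays centred on their medians the split was 3271 higher and 2125 lower. The result rests on 1 Foxo1KO/Foxo1AAA array, and the differences in X and Y transcripts and in markers of other cells described here are part of it.

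How far the genes changed in Foxo1KO returned was measured as a share of the knockout difference. Over the 2980 genes the median share recovered was 69.7% (25th to 75th percentile 11.9% to 122%), against 1.28% in simulated data with no recovery and no difference between array pairs. In 2375 genes (79.7%) the Foxo1KO/Foxo1AAA value lay on the WT side of Foxo1KO, against 52.8% in those simulations. The return was called in 1588 genes (1660 adjusted over the list alone), and 216 genes moved further away (234 adjusted over the list alone). Genes lowered in the knockout had a median share of 92.3%, and genes raised in it had 36.5%. Within array pairs, where Foxo1KO/Foxo1AAA is set against Foxo1AAA, the shares were 88.2% and 76.7%. Of the 2980 genes, 997 still differed from WT in the direction of the knockout difference. In Foxo1AAA without the knockout, 737 of them were also called apart from WT in that direction. Shares within array pairs therefore do not measure a return to WT.

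All 23 genes of naive and central T cells that were called in Foxo1KO lay on the WT side of it, with a median share of 98.5%. Foxo targets had a median share of 98.5% over 13 genes and the Treg signature 96.1% over 16. The naive and central list and the Foxo targets share Il7r, Klf2, Ccr7, S1pr1 and Pik3ip1, and Klf2 is the median gene of both. Their equal medians are therefore not separate results. Effector Treg genes had 83.4% over 25 genes and Th1 genes 52.6% over 19. The 41 cell cycle genes had a median share of -12.6% and 11 of them were called further from WT than in Foxo1KO. Within array pairs the medians were 87.9% for naive and central genes, 80.7% for Foxo targets and 73.4% for the Treg signature. They were 65.8% for effector Treg, 66.3% for Th1 and 79.7% for cell cycle genes. Of the 41 cell cycle genes, 38 still lay apart from WT, so their within-pair share does not show a return. Among genes at least 2-fold changed, the largest shares were those of Bambi-ps1 (291%), Tktl1 (231%), Susd1 (222%), Tubb2a (214%) and Aldh2 (213%), which passed beyond WT. The smallest were those of Cd5l (-273%), Plac8 (-263%), H2-Ab1 (-203%), H2-Eb1 (-161%) and Klrd1 (-158%), which are known from macrophages, antigen-presenting cells or NK cells. Without Foxo1KO replicate 1 the Foxo1KO calls of Tktl1 (adjusted p = 0.051, range over alternatives 6.1e-05 to 0.051), Plac8 (0.19, range 0.0023 to 0.27) and H2-Ab1 (0.051, range 3.7e-04 to 0.28) ended. H2-Eb1 also lost its call without that array (0.067, range 0.0011 to 0.13), and Plac8 and H2-Ab1 without WT replicate 1 (0.10 and 0.051). The Foxo1KO differences that these shares divide by moved without Foxo1KO replicate 1 from 1.00 to 0.43 for Plac8, from 1.09 to 0.44 for H2-Ab1 and from 1.18 to 0.71 for H2-Eb1. Without Foxo1KO replicate 2 they were 1.57 for Plac8 and 1.73 for H2-Ab1.

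**Figure D2:**
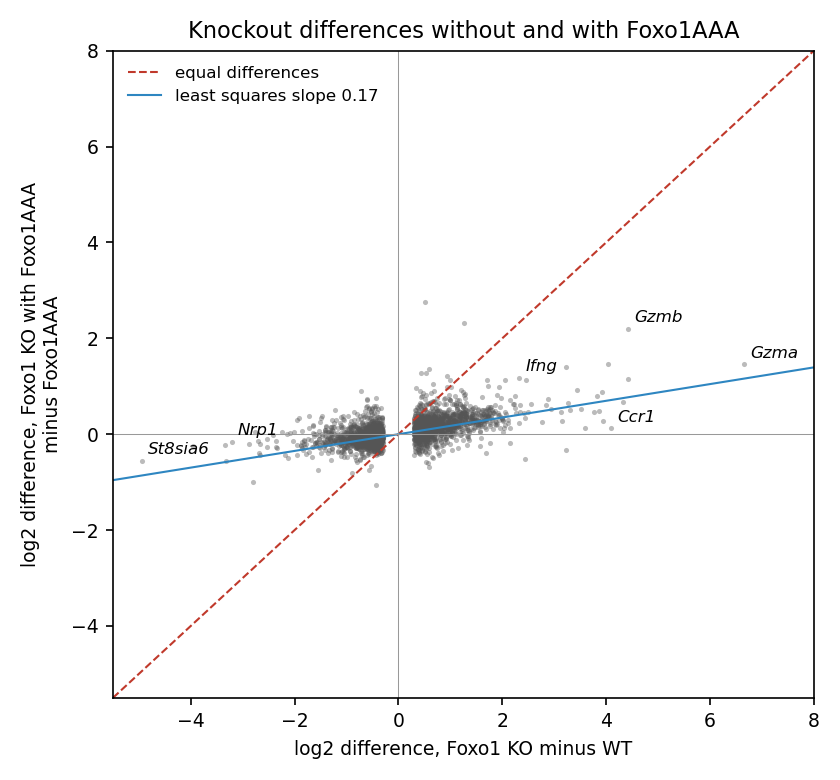
Knockout difference without Foxo1AAA (Foxo1KO minus WT, log2, horizontal axis) and with Foxo1AAA (Foxo1KO/Foxo1AAA minus Foxo1AAA, log2, vertical axis), with a point for each of the 2980 genes changed in Foxo1KO. The fitted line through the origin has a slope of 0.17 and is flatter than the line of equal differences.

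The knockout difference was then compared between the array pairs with and without Foxo1AAA, which share no array. Gzma was at least 101-fold higher in Foxo1KO than in WT but 2.74-fold higher in Foxo1KO/Foxo1AAA than in Foxo1AAA, and its interaction was log2 -5.20 (SE 0.19, adjusted p = 1.4e-05), a lower bound in size since its WT value was dim. St8sia6 was at least 30.8-fold lower without Foxo1AAA, and its interaction was 4.39 (SE 0.23, adjusted p = 1.2e-04), likewise a lower bound. The knockout difference was also smaller with Foxo1AAA for Nrp1 (interaction 3.06, SE 0.19, adjusted p = 1.5e-04), Id3 (2.06, SE 0.25, adjusted p = 0.0034), Il7r (1.85, SE 0.26, adjusted p = 0.0059) and Ccr7 (1.40, SE 0.17, adjusted p = 0.0040). Across the 2980 genes the slope was 0.17, against a mean of 0.97 and a lowest value of 0.96 in simulations with no recovery, and 0.49 in simulations with 50% recovery.

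The interaction passed the test for 811 genes, 383 higher and 428 lower, at this threshold. Without Foxo1KO replicate 2 the number was 443. Of the 2980 genes changed in Foxo1KO, 739 had a smaller difference with Foxo1AAA and 1 a larger one (1463 and 7 adjusted over the list alone). These genes were selected on the difference that the interaction subtracts, so selection favours smaller differences. The simulations gave no value for these counts, so how much of the imbalance is selection was not measured. By group, 30 of 41 cell cycle genes had a smaller difference (39 adjusted over the list alone, median interaction -1.12, camera adjusted p = 2.7e-32, adjusted p = 0.50 with an estimated correlation), among them Kif11 (-1.71) and Ttk (-1.54). The cell cycle genes were high in both groups with Foxo1AAA, so their small difference between those groups lay above WT. Genes of naive and central T cells had a positive interaction in 17 of 27 cases and a negative one in 1 (20 and 1 adjusted over the list alone, median 0.94, camera adjusted p = 8.1e-14, adjusted p = 0.50 with an estimated correlation). For Th1 genes it was negative in 10 of 22 cases and positive in 0 (14 and 1 adjusted over the list alone, median -0.81, camera adjusted p = 1.1e-09, adjusted p = 0.50 with an estimated correlation). Effector Treg genes had 9 negative and 2 positive of 30 (15 and 2 adjusted over the list alone, median -0.50, camera adjusted p = 1.4e-07, adjusted p = 0.50 with an estimated correlation), with Gzmb at -2.21 and Itgb1 at 1.57. Ifng had an interaction of -1.14 (SE 0.22, adjusted p = 0.020), and that call ended without Foxo1KO replicate 2 (adjusted p = 0.064, range over alternatives 0.0028 to 0.064). Foxo1 (-0.62, adjusted p = 0.17) and Klf2 (0.50, adjusted p = 0.24) were not called.

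The comparison of Foxo1AAA with WT measured the active form without the knockout. Genes known from macrophages and plasma cells were among the largest rises: Jchain rose at least 37.7-fold (log2 5.24, SE 0.34, adjusted p = 3.2e-05), C1qb at least 25.6-fold (log2 4.68, SE 0.29, adjusted p = 2.7e-05), Vcam1 19.3-fold (log2 4.27, SE 0.38, adjusted p = 1.5e-04) and Mrc1 at least 19.0-fold (log2 4.25, SE 0.30, adjusted p = 4.9e-05). The other leading rises were those of Gja1 (5.23), Atp6v0d2 (4.71), Iglv1 (4.10), Slc40a1 (3.93), Igkv8-30 (3.92) and Adgre4 (3.83). Ccr7 rose by 0.80 (SE 0.12, adjusted p = 0.0027), Gzma rose by at least 2.95 (SE 0.13, adjusted p = 8.2e-06), and Gzmb fell by 1.25 (SE 0.13, adjusted p = 2.9e-04). Foxo1 differed by -0.48 (adjusted p = 0.054) and was not called. It was called lower with a trended prior (0.027), with a robust prior (0.049) and without WT replicate 1 (-0.64, adjusted p = 0.014, range over alternatives 0.014 to 0.19).

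Xist fell by 6.70, with 6.04 on the Foxo1AAA array against 13.43 and 12.03 on the WT arrays. The other leading falls were those of Penk (-2.36), Dsg2 (-2.08), Ctse (-2.03), Ccr2 (-2.03), Gpr15 (-2.02), Ryr2 (-1.86), 2810410L24Rik (-1.63), Gm3715 (-1.59) and Ctla2b (-1.58). Cell cycle genes rose in 38 of 41 cases (39 adjusted over the list alone, median 1.25, camera adjusted p = 8.2e-25, adjusted p = 0.77 with an estimated correlation), led by Ube2c (2.40) and Kif11 (2.21). Of 11 heat shock genes 6 rose by both counts (median 0.45, camera adjusted p = 3.4e-04, adjusted p = 0.77 with an estimated correlation), led by Hmox1 (2.75) and Hspa1b (2.27). Of 17 glycolysis genes 8 rose and 2 fell by both counts (median 0.28, camera adjusted p = 0.037, adjusted p = 0.77 with an estimated correlation), with Hk2 at 0.92 and Tpi1 at 0.75. Of 25 Foxo targets 6 rose and 1 fell by both counts (median 0.12, camera adjusted p = 0.045, adjusted p = 0.77 with an estimated correlation), with Klf4 at 1.33 and Cited2 at 1.18. Without WT replicate 2 the calls of Foxo targets (adjusted p = 0.099, range over alternatives 0.0024 to 0.49) and glycolysis (0.050, range 4.9e-04 to 0.19) ended.

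Markers of other cells rose beside these groups. Of 13 myeloid markers 10 rose and 1 fell by both counts (median 1.52, camera adjusted p = 7.4e-06, adjusted p = 0.77 with an estimated correlation), with Tyrobp at 3.40 and Adgre1 at 3.34. Of 10 dendritic cell markers 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.91, camera adjusted p = 1.0e-04, adjusted p = 0.77 with an estimated correlation), with H2-Aa at 3.63 and H2-Ab1 at 3.14. Of 12 B cell markers 8 rose and 0 fell (8 and 2 adjusted over the list alone, median 0.97, camera adjusted p = 0.0014, adjusted p = 0.77 with an estimated correlation), with Ms4a1 at 2.78 and Bank1 at 2.24. With a robust variance prior the calls of Ms4a1 (adjusted p = 0.27, range over alternatives 8.4e-04 to 0.27) and Bank1 (0.12, range 1.4e-04 to 0.12) ended. Of 6 erythroid markers 2 rose (3 adjusted over the list alone, median 0.35, camera adjusted p = 0.044, adjusted p = 0.77 with an estimated correlation), namely Car2 (2.29) and Slc4a1 (1.67), and the call of this list ended with the lowest 50% of genes left out (adjusted p = 0.099, range over alternatives 0.0029 to 0.099). The lists of naive and central (median 0.17, camera adjusted p = 0.26), Th1 (0.17, 0.43) and effector Treg genes (-0.08, 0.86) did not shift, although the naive and central list was called higher with the mean of probe sets (0.029, range over alternatives 0.029 to 0.86). The effector Treg mean was 0.03 and its test pointed up, against the sign of its median.

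**Figure D3:**
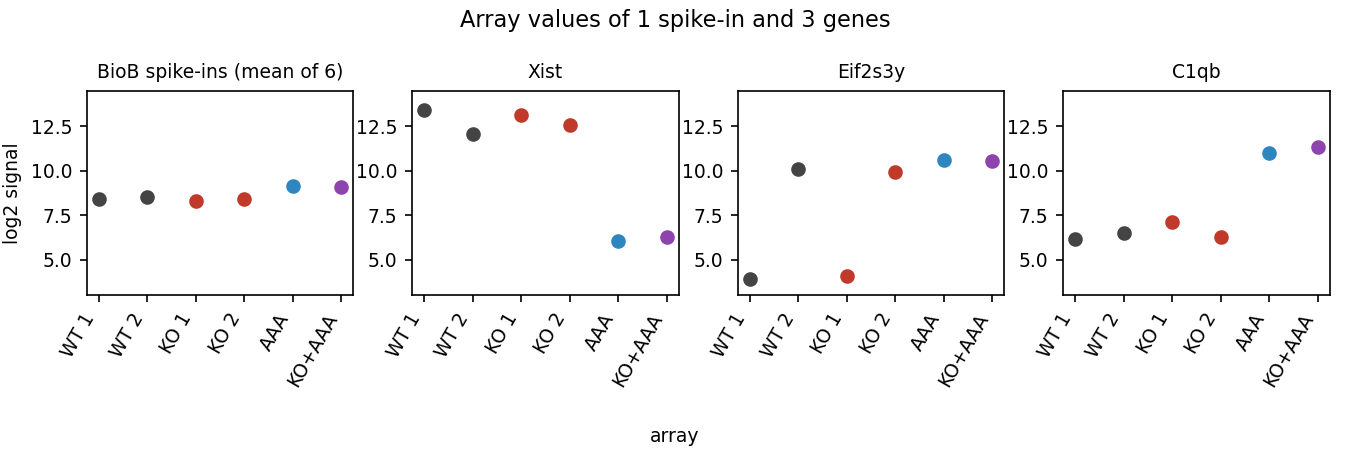
Log2 signal on each of the 6 arrays for the mean of the 6 BioB hybridization control probe sets, for Xist, for the Y chromosome gene Eif2s3y and for the complement gene C1qb. The BioB mean is 9.13 and 9.07 on the Foxo1AAA and Foxo1KO/Foxo1AAA arrays and 8.28 to 8.51 on the other 4, and Xist is below 6.3 on those 2 arrays and above 12 on the other 4.

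In total 3758 genes changed between Foxo1AAA and WT, 1834 higher and 1924 lower, and of those changed at least 2-fold 442 were higher and 74 lower. With arrays centred on their medians the split was 2694 higher and 1202 lower, since that scaling moved the median gene by 0.11 in this comparison. Of the lists that camera called in this comparison, fry called only heat shock. The Foxo1AAA array stands alone in its group. It and the Foxo1KO/Foxo1AAA array differed from the other 4 in the BioB control, in Xist and in the markers of other cells. The 3' minus 5' signal of Gapdh was 0.10 and 0.19 on them against 0.32 to 0.65 on the other 4, and that of Actb 0.62 and 0.66 against 0.70 to 0.76.

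Foxo1KO/Foxo1AAA cells were compared with WT to see how far they differed from it. Gzma was at least 21.2-fold higher than in WT (log2 4.40, SE 0.13, adjusted p = 1.0e-06), having also risen in Foxo1AAA alone, and Ifng was 2.69-fold higher (log2 1.43, SE 0.15, adjusted p = 3.4e-04). Ccl3 was at least 7.70-fold higher (log2 2.95, SE 0.20, adjusted p = 2.7e-05) and lay further from WT than in Foxo1KO. Il7r (0.88, SE 0.18, adjusted p = 0.0090) and Ccr7 (0.54, SE 0.12, adjusted p = 0.013) were above WT, whereas Klf2 differed by -0.01 (adjusted p = 0.97). Foxo1 was lower by log2 -1.54 (SE 0.16, adjusted p = 2.6e-04). The leading rises were again Gja1 (6.21), Atp6v0d2 (5.02), C1qb (4.99), Jchain (4.92), Cd5l (4.66), Vcam1 (4.62), Mrc1 (4.36), Adgre4 (4.32) and Mgst1 (4.14). The WT values of C1qb, Jchain and Mrc1 were dim, so their differences are lower bounds and the order is not fixed. Xist fell by 6.46, and the other leading falls were those of Ctse (-2.30), Gpr15 (-1.72), Ryr2 (-1.60), Tktl1 (-1.45), Ccr6 (-1.38), Pisd-ps3 (-1.35), Cc2d2a (-1.32) and Gt(ROSA)26Sor (-1.31).

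Cell cycle genes rose in 38 of 41 cases (39 adjusted over the list alone, median 1.55, camera adjusted p = 5.8e-26, adjusted p = 0.70 with an estimated correlation), led by Aurkb (2.76) and Ube2c (2.72). Of 22 Th1 genes 12 rose and 1 fell (14 and 3 adjusted over the list alone, median 0.55, camera adjusted p = 2.5e-04, adjusted p = 0.70 with an estimated correlation). Of 30 effector Treg genes 12 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.36, camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation), with Ccl5 at 2.04 and Il10 at 1.79. That call ended with the lowest 50% of genes left out (adjusted p = 0.18), with cyclic loess (0.094) and without WT replicate 2 (0.072, range over alternatives 2.4e-04 to 0.18). Lists of heat shock (median 0.39, camera adjusted p = 0.0031), glycolysis (0.36, 0.012), interferon response (0.21, 0.031) and immediate early genes (0.26, 0.049) were also shifted higher, each at adjusted p = 0.70 with an estimated correlation. The last 3 of these calls ended with the lowest 50% of genes left out (adjusted p = 0.075, 0.27 and 0.33). The naive and central list did not shift (median -0.05, mean 0.06, camera adjusted p = 0.70). Myeloid markers rose in 10 of 13 cases by both counts (median 2.81, camera adjusted p = 1.1e-06, adjusted p = 0.70 with an estimated correlation), with Csf1r at 3.73 and Fcer1g at 3.59. Dendritic cell markers rose in 9 of 10 cases and fell in 1 by both counts (median 1.07, camera adjusted p = 1.9e-04, adjusted p = 0.70 with an estimated correlation). B cell markers rose in 7 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone, median 0.81, camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation). CD8 T and NK cell markers rose in 4 of 7 cases and fell in 0 (4 and 1 adjusted over the list alone, median 1.06, camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation), a call that ended with the lowest 50% of genes left out (adjusted p = 0.66, range over alternatives 0.0025 to 0.66). In total 4193 genes changed, 2317 higher and 1876 lower, and 2840 higher and 1257 lower with arrays centred on their medians. Of those changed at least 2-fold, 590 were higher and 48 lower.

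Foxo1KO/Foxo1AAA was set against Foxo1AAA to measure the knockout in the presence of the active form, with 1 array on each side. Ubd, a ubiquitin-like protein, was at least 6.72-fold higher (log2 2.75, SE 0.14, adjusted p = 2.4e-04), the chemokine Ccl3 at least 5.01-fold (log2 2.32, SE 0.23, adjusted p = 0.013), Gzmb 4.60-fold (log2 2.20, SE 0.14, adjusted p = 7.4e-04) and Gzma 2.74-fold (log2 1.46, SE 0.15, adjusted p = 0.017). F11r (1.52), the monocyte marker Cd14 (1.49), Gm4951 (1.40), Lpl (1.27) and Bcl2l15 (1.13) were also higher. Igha, an immunoglobulin heavy chain of plasma cells, fell by 2.47 (SE 0.13, adjusted p = 2.4e-04) and was the only gene called lower. Foxo1 (-1.05, SE 0.18, adjusted p = 0.083) and Ifng (1.18, SE 0.18, adjusted p = 0.054) were not called. Foxo1 was called with median centring (0.012), with a trended prior (0.039) and without WT replicate 1 or 2 (0.010 each, range over alternatives 0.010 to 0.17). Ifng was called in these settings too (0.013, 0.037 and 0.0069) and with no filter (0.036), the mean of probe sets (0.046) and a robust prior (0.041, range over alternatives 0.0069 to 0.13).

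These 10 genes, 9 higher and 1 lower, were all that passed, and 1364 genes had an unadjusted p under 0.05. The number was 63 higher and 24 lower with arrays centred on their medians, 3 and 1 with cyclic loess, and 91 without WT replicate 1 or without WT replicate 2. The calls of Gm4951 (adjusted p = 0.057, range over alternatives 0.0020 to 0.082), Lpl (0.065, range 0.0033 to 0.082) and Bcl2l15 (0.082, range 0.0065 to 0.082) ended without Foxo1KO replicate 1 or 2. With cyclic loess the calls of Gzma (adjusted p = 0.082, range over alternatives 8.0e-04 to 0.082), Ccl3 (0.066, range 6.9e-05 to 0.066) and F11r (0.068, range 8.5e-04 to 0.068) ended. Of 22 Th1 genes 3 were higher (8 adjusted over the list alone, median 0.44, camera adjusted p = 7.6e-12, adjusted p = 0.66 with an estimated correlation). The cell cycle list was shifted higher by camera at the preset correlation, without a called member by either count (median 0.29), but not with an estimated correlation. That estimate was 0.57, far above the preset 0.01. With 1 array on each side, camera compares genes here and has no replicate of either group, so this shift is not established. Effector Treg genes were also shifted higher, with 1 called member (2 adjusted over the list alone, median 0.27, camera adjusted p = 1.3e-07, adjusted p = 0.74 with an estimated correlation). The naive and central list was shifted lower with 0 called members by both counts (median -0.14, camera adjusted p = 3.0e-04, adjusted p = 0.74 with an estimated correlation). CD8 T and NK cell markers moved with the Th1 genes, with 0 called members (4 adjusted over the list alone, median 0.48, camera adjusted p = 4.5e-04, adjusted p = 0.66 with an estimated correlation). That call ended with no filter on dim genes (adjusted p = 0.59, range over alternatives 2.7e-05 to 0.59). Myeloid markers were shifted higher with 1 called member by both counts (median 0.15, camera adjusted p = 0.012, adjusted p = 0.74 with an estimated correlation), a call that ended with no filter (0.054) and with the lowest 50% of genes left out (0.30, range 0.0019 to 0.30). B cell markers had 0 called members by both counts (median -0.16, camera adjusted p = 0.056) and were called lower in 5 alternatives: without Foxo1KO replicate 1 or 2 (0.016 each), without WT replicate 1 or 2 (0.034 each) and with median centring (0.041, range 0.016 to 0.50). Interferon response genes (median 0.18, camera adjusted p = 0.0090) and the Treg signature (0.12, 0.029) were shifted higher and heat shock genes lower (-0.11, 0.029), each at 0.74 with an estimated correlation. The Treg signature and heat shock calls ended with no filter (0.063 and 0.084) and with the mean of probe sets (0.10 and 0.060, ranges 0.0068 to 0.10 and 0.013 to 0.084).

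**Figure D4:**
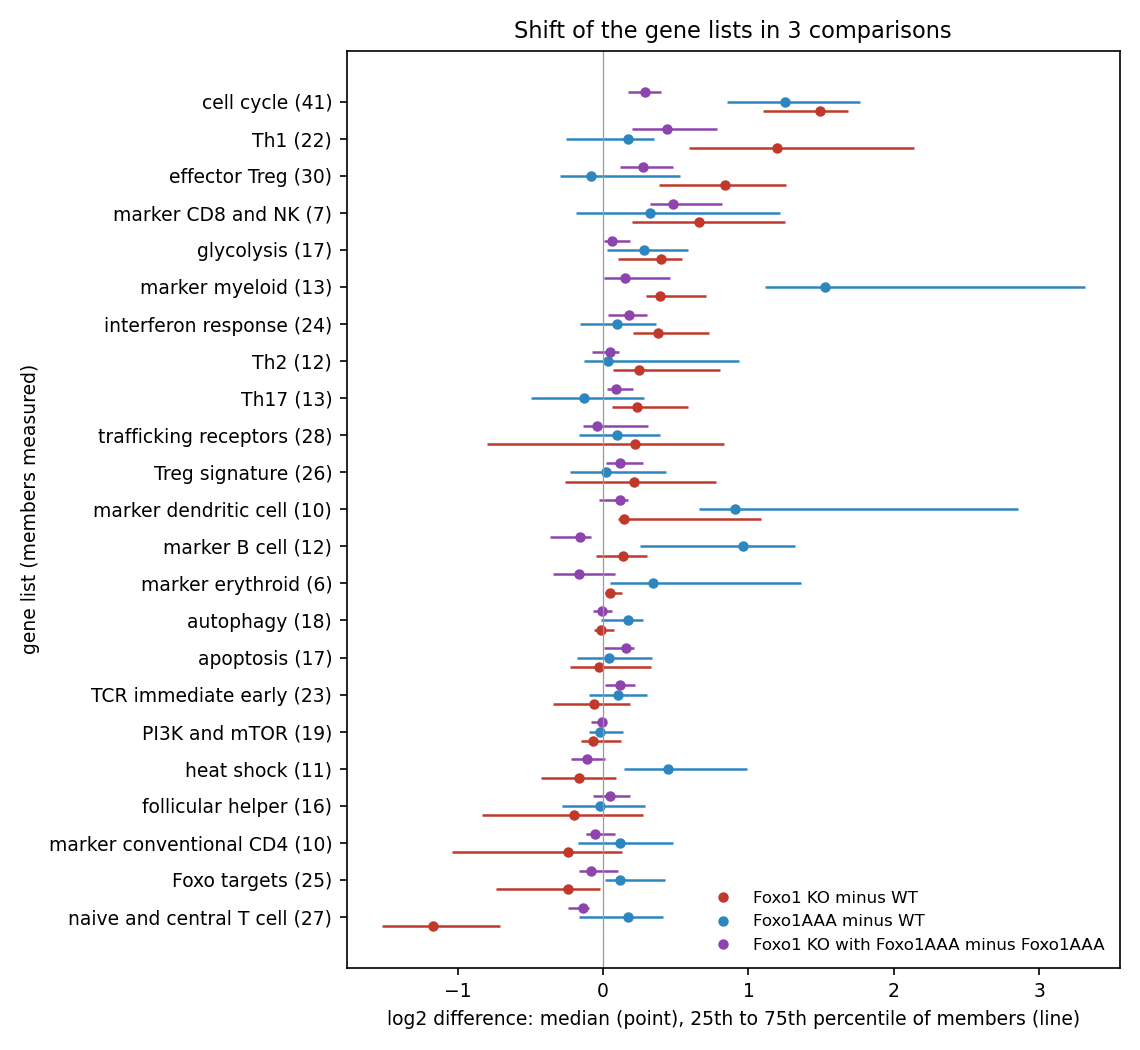
Median log2 difference of each of the 23 gene lists in 3 comparisons, with bars from the 25th to the 75th percentile of the list's members. The naive and central T cell list lies at -1.17 in Foxo1KO against WT, 0.17 in Foxo1AAA against WT and -0.14 in Foxo1KO/Foxo1AAA against Foxo1AAA, and the cell cycle list at 1.50, 1.25 and 0.29.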

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

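The tests of hybridization, of myeloid RNA for the genes higher with Foxo1AAA and for the granzyme genes, of kept Foxo1 and of NK cells were chosen after their results were seen. The test of T cell genes on the Foxo1AAA array replaced an earlier, void test after that test's value was seen.

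The knockout difference itself differed with and without Foxo1AAA, by a test of the interaction, for 811 genes, and this drew attention to the genes and lists given here. The largest positive interactions were those of St8sia6 (4.39), H2-Ob (3.69), Prg4 (3.11), Nrp1 (3.06), Nt5e (2.80), Btbd11 (2.75), Gpr34 (2.67), Ms4a6c (2.57), Pde4b (2.48) and Dapl1 (2.45). The largest negative interactions were those of Gzma (-5.20), Ccr1 (-3.96), Atp8b4 (-3.67), Arnt2 (-3.66), Jchain (-3.54), Tgm2 (-3.48), Anxa1 (-3.37), Ifitm3 (-3.30), Ermn (-3.26) and Ifitm2 (-3.04). H2-Ob, Prg4 and Gpr34 in Foxo1KO, Ccr1 in WT and Ermn in WT and Foxo1AAA lay below the dimmest tested mean of 5.47, so the sizes and order of their interactions are uncertain, as are those resting on other dim values such as St8sia6 in Foxo1KO and Gzma in WT. With a robust variance prior the interactions of Dapl1 (adjusted p = 0.092, range over alternatives 2.9e-04 to 0.092) and Jchain (0.089, range 5.9e-05 to 0.089) were no longer called.

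The interaction also shifted 11 gene lists by camera, 0 with an estimated correlation and 0 by fry. Its median was positive for naive and central T cell genes (0.94), immediate early genes (0.26), conventional CD4 T cell markers (0.23), Foxo targets (0.19) and follicular helper genes (0.13). It was negative for cell cycle (-1.12), Th1 (-0.81), effector Treg (-0.50), glycolysis (-0.33), Th2 (-0.30) and interferon response genes (-0.21). The follicular helper call ended without Foxo1KO replicate 2 (adjusted p = 0.077) or WT replicate 1 (0.12, range over alternatives 0.025 to 0.13), and the Th2 call without Foxo1KO replicate 1 (0.16, range 0.015 to 0.16). The conventional CD4 T cell marker call ended with the lowest 50% of genes left out (0.17) and with cyclic loess (0.060, range 0.011 to 0.17). The follicular helper call also ended with no filter (0.053) and with the mean of probe sets (0.13), and the Th2 call with no filter (0.12), the lowest 50% left out (0.052) and cyclic loess (0.056). Markers of B cells (0.0012, range 0.0012 to 0.69), myeloid cells (0.0023, range 0.0023 to 0.69) and dendritic cells (0.0012, range 0.0012 to 0.57), not called at first, were called lower without Foxo1KO replicate 2, and also without WT replicate 2 (0.025, 0.026 and 0.025). CD8 T and NK cell markers were called lower without WT replicate 1 (0.048) or 2 (0.032, range 0.0065 to 0.88).

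A signal outside the genes also drew attention. The BioB hybridization controls, which are added to the labelled sample and hold no mouse RNA, were higher by 0.70 on average on the Foxo1AAA and Foxo1KO/Foxo1AAA arrays than on the other 4. Among the probe sets with no single gene name, 1131 of 5197 tested changed between Foxo1KO and WT, 186 higher and 945 lower.

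The Foxo1AAA and Foxo1KO/Foxo1AAA arrays stood apart from the WT and Foxo1KO arrays. For the genes lower in Foxo1AAA, dilution by other cells' RNA is argued against, among bright genes, by 7 T cell genes. Their median difference from WT was 0.23 with 0 called lower by limma. Their WT means were 10.8 to 13.3, where differences can be understated, so they do not decide this for dim genes. A plain contrast of males with females is argued against, since the Y chromosome genes lay only 0.34 above the highest of the other arrays. That highest array was WT replicate 2, which also held Xist. The sex make-up did differ: Xist measured 6.04 and 6.27 on the Foxo1AAA and Foxo1KO/Foxo1AAA arrays, against 12.03 to 13.43 on the other 4. A different sex make-up as the whole cause outside the X and Y chromosomes is argued against by a slope of -0.044 between the Foxo1KO replicates, which differ in Y transcripts. Its bootstrap SD of 0.0066 resampled 3640 genes of 1 pair of arrays and does not measure spread between mice. Replicate 2 still held Xist (12.59, against 13.14 on replicate 1), so the pair differs in sex only in part, which weakens this test. A separate hybridization fits the BioB gap of 0.56, against a range of 0.23 among the other 4 arrays, and the design confounds it with Foxo1AAA, which stays open as an untested biological explanation.

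Myeloid cells are a candidate source of the genes higher in Foxo1AAA, as a hypothesis. The median myeloid marker was 1.52 above WT on the lower of those 2 arrays, Csf1r measured 11.99 and 12.38 on them against 8.65 in WT, and Lyz2 10.50 and 10.41 against 7.25. The myeloid list shares 0 of its 13 measured members with the other lists. A sort that excludes cells with Csf1r or Adgre1 protein would remove such cells and test this.

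The knockout difference was smaller between the Foxo1KO/Foxo1AAA and Foxo1AAA arrays than between Foxo1KO and WT. A compressed scale is argued against by the slope of the Foxo1AAA array on WT over all genes, which was 1.01. Selection of genes is argued against by simulations with no recovery, whose lowest slope was 0.96 against the observed 0.17. Cells that kept Foxo1 stay open: the Foxo1 probe sets differed by a median of -0.92 between those arrays, and Foxo1 was called lower there than in WT (-1.54) and Foxo1KO (-1.10), which goes against them, but the deleted part was not given and a probe set outside it checks nothing. Action of Foxo1AAA in place of the missing Foxo1 stays a hypothesis, and the cell cycle genes were high on both arrays.

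Granzyme and Th1 genes were higher in Foxo1KO than in WT. RNA from CD8 T cells is argued against by Cd8a and Cd8b1, whose larger difference was 0.19, while Gzma rose by at least 6.66. RNA from NK cells was not decided: Tyrobp and Fcer1g, abundant in those cells, had a larger upper 95% bound of 0.93, whereas Klrc1 (4.04), Klrd1 (1.23) and Xcl1 (1.27) rose. RNA from myeloid cells as the whole cause is argued against by the arrays with more of it. The myeloid list lay 0.39 above WT in Foxo1KO but 1.52 and 2.81 on the Foxo1AAA and Foxo1KO/Foxo1AAA arrays. On those 2 arrays the 75th percentile of the Th1 list reached at most 1.05, against a median of 1.19 in Foxo1KO. In Foxo1AAA Gzmb fell by 1.25, although Gzma rose by at least 2.95. Loss of Foxo1 within the Treg cells stays a hypothesis, which a sort excluding cells with NK receptors and myeloid markers would test.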

How the results depend on the processing

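The cyclic loess, median-centred, filter, prior, threshold and leave-one-out settings were planned, and those within array pairs and without marker and X or Y genes were chosen after seeing the data. Of 2689 values of 248 named results under alternatives, 2610 kept direction and side of the threshold, 55 lost the call, 15 gained it and 9 turned direction. Against WT in Foxo1KO, the mean of all probe sets turned Ighm (0.84), Foxo3 (-0.040) and Foxo4 (0.10), and cyclic loess turned Foxo4 (0.0015). Leaving out 1 array, Foxo3 ranged from -0.084 to 0.12 and Foxo4 from -0.18 to 0.070. Klf2 in Foxo1KO/Foxo1AAA against WT was 0.067 with median centring and -0.075 to 0.055 without 1 array. The cause was not tested. These Foxo3, Foxo4 and Klf2 differences were not called in the first place.

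The number of genes changed between Foxo1KO/Foxo1AAA and Foxo1AAA, 10 in the fit reported, moved most: 73 with no filter, 3 with the lowest 50% of genes left out, 41 with the mean of probe sets, 4 with cyclic loess, 87 with median centring, 30 with a trended prior, 38 with a robust prior, 77 at adjusted p under 0.10, 18 with every probe set tested, 32 without 473 marker and X or Y genes, and 7 to 91 without 1 array. With the lowest 50% left out, 3423 genes changed between Foxo1KO/Foxo1AAA and Foxo1KO and 2236 between Foxo1AAA and WT. Most of the lost calls were of lower genes: 1158 and 736 were lower, against 2760 and 1924 in the fit reported. Genes changed between Foxo1KO and WT numbered 2829 with that filter, against 2980. With every probe set tested, 5936 changed between Foxo1AAA and WT and 6325 between Foxo1KO/Foxo1AAA and WT. The interaction gave 1272 genes at adjusted p under 0.10 and 443 to 917 without 1 array. Requiring at least a 2-fold change left 584, 796, 516 and 638 genes in the first 4 comparisons and 440 in the interaction. With an estimated correlation 0 lists shifted in Foxo1KO, against 12 by camera and 13 by fry. In each comparison with a Foxo1AAA array fry called fewer lists than camera. Of the lists that camera called, it kept only heat shock in Foxo1AAA against WT. For Foxo1KO/Foxo1AAA it kept naive and central, Foxo targets, Th1 and heat shock against Foxo1KO. Against WT it kept cell cycle, glycolysis, heat shock and CD8 T and NK markers, and against Foxo1AAA the last 2 of these.

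The median share recovered was 65.8% with the lowest 50% left out, 65.3% with cyclic loess, 72.9% with median centring, 67.5% with a trended prior, 64.1% for genes at least 2-fold changed, 76.0% for the 200 genes with the smallest p, 84.8% with Foxo1AAA as the reference, 63.3% as a least squares slope, 82.3% within array pairs and 63.4% to 71.3% without 1 array. The slope without shared arrays was 0.187 with the mean of probe sets and 0.165 to 0.174 without 1 array.

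With the replicate number as a replicate block, 2458 genes and 12 lists changed in Foxo1KO, 2435 of the genes among the 2980. The deviations of same-numbered arrays correlated at r = -0.10 across genes, although replicate 2 of both groups carried Y chromosome transcripts and replicate 1 of neither did. The labels do not say what the number marks. The lone Foxo1AAA and Foxo1KO/Foxo1AAA arrays could not be left out, and arrays left alone by leaving out a replicate were assumed to vary like the other groups. Dim genes near background limit what the arrays can resolve, and the number of arrays limits the precision.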

Other observations

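No test in this part was planned; the values given here were looked at after the comparisons had been made.

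The Foxo1AAA and Foxo1KO/Foxo1AAA arrays differed from WT and from Foxo1KO in many of the same genes. Across 13645 genes the difference of Foxo1AAA from WT and that of Foxo1KO/Foxo1AAA from Foxo1KO, which share no array, correlated at r = 0.72, and genes are not independent replicates. Called higher in both were 1255 genes, against 359 for independent calls, and called lower in both were 1276, against 389. Prg4 was among them, at 12.14 and 11.91 on the Foxo1AAA and Foxo1KO/Foxo1AAA arrays against 8.46 and 8.58 in WT and 5.25 and 5.10 in Foxo1KO. Both of those arrays also differed from the rest in the hybridization controls, which the design confounds with Foxo1AAA, and in markers of other cells, as the report describes.

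Gt(ROSA)26Sor, a locus often used to insert transgenes in mice, measured 10.27 ± 0.13 in WT and 9.94 ± 0.08 in Foxo1KO (SD, n = 2 each), 9.03 on the Foxo1AAA array and 8.96 on the Foxo1KO/Foxo1AAA array. The labels do not give the site of the Foxo1AAA transgene. The Y chromosome gene Eif2s3y measured 3.91 and 10.09 on the WT arrays, 4.05 and 9.91 on the Foxo1KO arrays, 10.59 on the Foxo1AAA array and 10.56 on the Foxo1KO/Foxo1AAA array. Replicate 2 of WT and of Foxo1KO thus held Xist and Y chromosome transcripts together.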
